A study of Mus musculus with 6 samples.

How the data were processed

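Lung ILC2s of IL-33-treated wild-type mice were sorted into Nrp1high and Nrp1low cells and sequenced as 3 libraries per group. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected with oligo(dT) beads and fragmented, and strand-marked libraries with unique molecular identifiers were read as paired ends on an Illumina instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2, edgeR and the mouse build mm9, without stating the role of each. The gene identifiers match a newer annotation than that build (24135 of 24186, or 99.8%, are in GENCODE M21), so no coordinates are given.

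The authors deposited a table of FPKM values per gene and library, which are scaled to transcript length and library size and are not counts. The deposited log2 fold changes and fold ratios equal the ratio of the group means of FPKM within 0.001 in all 24186 rows, with a mean of 0 replaced by 1e-04. The deposited q-values equal the Benjamini-Hochberg adjustment of the deposited p-values; which tool gave those p-values is not given in the sources used here. The lowest value above 0 is 1e-06, so read counts could not be recovered from the low values and depth is unknown. Exact zeros occur at levels where genes are otherwise seen: of 11125 genes with a mean of at least 1 FPKM, 898 are listed at 0 in at least 1 library, and of 2656 with a mean of at least 20 FPKM, 1 is. A gene at 0 is therefore called listed at 0, and the libraries of a group with such a value are given singly. No fold is given against a group listed at 0 in all its libraries, and the log2 difference of a gene with some libraries at 0 rests in part on those zeros. The identifier Gapdh averages 20.1 FPKM in Nrp1high, low for that gene, which has many processed pseudogenes; levels of genes with near-identical copies, such as histone, Mup and Serpina1 genes, and of overlapping genes are uncertain.

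Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), as Nrp1low minus Nrp1high, with Benjamini-Hochberg adjustment and a threshold of 0.05. 42 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with lists of at least 3 tested genes, and again with an estimated correlation and with fry. Where camera's own variance prior had to be set, the trend was kept, a choice made after seeing the data. KEGG pathways with 5 to 500 tested genes were tested for called genes by one-sided Fisher's exact tests, with the tested genes that carry any KEGG annotation as background. Single genes were also compared by exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1; figures were drawn with matplotlib 3.10.9. Data on 11125 genes were simulated with 1 spread per gene, from the variances of both groups averaged. On them the test recovered 55 of 100 genes changed by 1 log2 unit and 91 of 100 changed by 2. Of 160 calls, 14 were false. The real Nrp1high libraries correlated less with each other than the Nrp1low libraries did. A spread that differs between the groups was not simulated. The changed genes were drawn only from the 4226 genes with a mean of at least 10 FPKM, so recovery at lower levels was not measured. The simulated raised list and pathway were called, and 0 of 38 lists without a raised gene were. The simulated noise was independent between genes, so it cannot show how often lists of correlated genes are called wrongly.

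Apart from camera's variance prior and the alternatives described below as added, the grouping, the test, the lists and the alternatives were fixed before the data were examined. So was the rule for named genes. It takes Nrp1, a fixed set of ILC2 genes, the 10 highest and 10 lowest log2 differences among called genes with a mean of at least 5 FPKM and no overlap between groups (leaving out predicted genes, pseudogenes and receptor segments), and up to 4 members of each list discussed. Alb, Apoa2, Fabp1, Ttr, Malat1, mt-Rnr1, mt-Rnr2, Gimap4, Chil3, Psmb3, Psmc5, Cd14 and Cd68, the NK cell genes given at or near 0, and the T cell receptor segments were named after their values were seen. So was the list of 33 hepatocyte genes written, none of which is on another list; Trf and Apoc1 were left off it because macrophages also express them.

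The alternatives chosen beforehand were pseudocounts of 0.1 and 5, no level filter, a filter at 5 FPKM, TMM and quantile scaling, a constant prior variance, a replicate block, each library left out in turn, the authors' deposited q, and other settings of the list and pathway tests. Scaling by median ratios and camera with a constant prior variance were added after seeing the data. In the test of dilution among the closing observations, a first version used 12 ILC2 genes picked after their values were seen; it was replaced by the ILC2 transcription factor and receptor lists fixed earlier. The tests of scaling there for the macrophage and cell cycle genes first counted all list genes called under each scaling, and were changed to follow the genes called here.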

Results

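The data are bulk RNA-seq of group 2 innate lymphoid cells (ILC2s) sorted from the lungs of wild-type mice given IL-33. ILC2s are lymphocytes without rearranged antigen receptors that make type 2 cytokines when IL-33 reaches their receptor ST2. Cells with a high and a low level of neuropilin-1 (Nrp1), a surface co-receptor for semaphorins and vascular endothelial growth factor, were sorted separately, with 3 libraries per group and 6 in all. The values are FPKM per gene for 24186 genes, and they sum to between 403072 and 433955 per library. Read counts per library were not used here, so the depth behind each value is unknown. Nothing in the labels says that the replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical. Across genes, the log2 values correlated at 0.901 to 0.931 among the Nrp1high libraries and at 0.961 to 0.968 among the Nrp1low libraries. Between the groups they correlated at 0.885 to 0.924, which overlaps the range among the Nrp1high libraries. The first principal component, with 45.0% of the variance, separated the groups. The second, with 23.7%, set Nrp1high replicate 1 (44.5) apart from Nrp1high replicate 2 (-46.4). Differences are given as Nrp1low minus Nrp1high on the log2(FPKM + 1) scale with their standard error (SE), which understates the change of genes at low levels, and levels as mean ± SD with n = 3 per group.

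The sort gene was looked at first, as a check of the labels. Nrp1 (ENSMUSG00000025810) measured 10.5, 7.43 and 9.57 FPKM in the Nrp1high libraries. It measured 0.449 FPKM in Nrp1low replicate 1 and was listed at 0 in the other Nrp1low libraries. The log2 difference was -3.15 ± 0.29 (SE; limma adjusted p = 0.000501). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 values allow. Because the cells were sorted on Nrp1, this difference is no finding between the groups. In the authors' deposited table the log2 fold change of Nrp1 is -5.93 with q = 0.226.

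The comparison the design names is between the transcriptomes of Nrp1low and Nrp1high ILC2s. Genes of DNA replication and mitosis, the ILC2 products Areg and Il13, the receptors Klrg1 and Il2ra, and Il10, Gzma, Gzmb and Nkg7 were higher in Nrp1low cells. Macrophage and monocyte genes, MHC class II genes, several chemokines, Csf2 and Fos were lower. Of 11125 tested genes, 998 differed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 427 of them higher and 571 lower in Nrp1low, and 2683 had an unadjusted p under 0.05. By at least 1 log2 unit, 194 were higher and 415 lower. The values of the groups did not overlap for 3329 tested genes (29.9%), where chance gives 10%. The count was 527 (177 higher, 350 lower), 566 (203 and 363) and 481 (160 and 321) without Nrp1low replicate 1, 2 and 3 in turn, and 473 (196 and 277) with no filter on low values. With a filter at 5 FPKM the balance turned, with 476 higher and 465 lower.

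Cell cycle genes were higher in Nrp1low cells. Of the 27 tested genes of the mitosis list, 19 rose and none fell, with a median log2 difference of 1.31, and 25 rose when adjusted over the list alone. Of the 25 tested S phase genes, 16 rose and none fell, with a median of 1.08, and 19 rose when adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, measured 67.3 ± 4.45 FPKM in Nrp1low against 22.2 ± 3.31 in Nrp1high (log2 difference 1.56 ± 0.15), and Ccna2, which encodes cyclin A2, measured 38.0 ± 2.17 against 11.2 ± 1.76 (1.68 ± 0.16). Mcm5, a subunit of the replicative helicase, measured 70.2 ± 4.29 against 27.0 ± 1.89 FPKM (1.35 ± 0.13). Rrm2, a subunit of ribonucleotide reductase, measured 105 ± 3.46 against 39.2 ± 5.75 FPKM (1.41 ± 0.14). Mki67, the gene of the proliferation marker Ki-67, measured 7.68 ± 0.598 against 4.14 ± 0.318 FPKM and missed the threshold (0.76 ± 0.20, limma adjusted p = 0.0587). Both lists passed camera, a competitive test against all other genes (adjusted p = 8.97e-18 for mitosis and 1.04e-14 for S phase), and they held with an estimated inter-gene correlation (adjusted p = 0.0170 for both).

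The effector cytokines of ILC2s moved in both directions. Of the 12 tested, 3 rose, 3 fell and 6 did not pass the test, and the list as a whole was not called (camera adjusted p = 0.702). Adjusted over the list alone, 4 rose and 4 fell. Its median (0.33) and its mean (-0.028) had opposite signs. Areg, which encodes the growth factor amphiregulin, rose from 402 ± 58.1 FPKM in Nrp1high to 795 ± 95.8 in Nrp1low (0.99 ± 0.13, limma adjusted p = 0.00256). Il13 measured 16.4 ± 6.48 against 37.7 ± 4.77 FPKM (1.21 ± 0.25, adjusted p = 0.0236). The call for Il13 was lost with no filter on low values, with a constant prior variance, and without Nrp1high replicate 1 or 2 or any of the Nrp1low replicates, with log2 differences of 1.11, 1.01, 1.31, 1.19 and 1.13. Csf2, the gene of the cytokine GM-CSF, went the other way, from 603 ± 43.8 FPKM in Nrp1high to 138 ± 13.2 in Nrp1low (-2.13 ± 0.10, adjusted p = 1.67e-05). Ccl1 (30.3 ± 2.01 against 3.34 ± 0.883 FPKM) and Tnf (13.7 ± 7.03 against 1.49 ± 0.620 FPKM) were lower in Nrp1low as well, Tnf not called with no filter on low values. Il4 measured 14.4 ± 3.77 FPKM in Nrp1high and 24.5 ± 5.95 in Nrp1low and missed the threshold (adjusted p = 0.121). Il5 was below the level filter, at 0.118, 0 and 0.695 FPKM in Nrp1high and 0.867, 0.806 and 2.24 FPKM in Nrp1low. Zeros and values near 0 in this table can be failed estimates, so the levels of Il5 are not read as its absence. Il9 was listed at 0 in 5 libraries and at 2.20 FPKM in Nrp1high replicate 1, and it was not tested either.

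**Figure D1:**
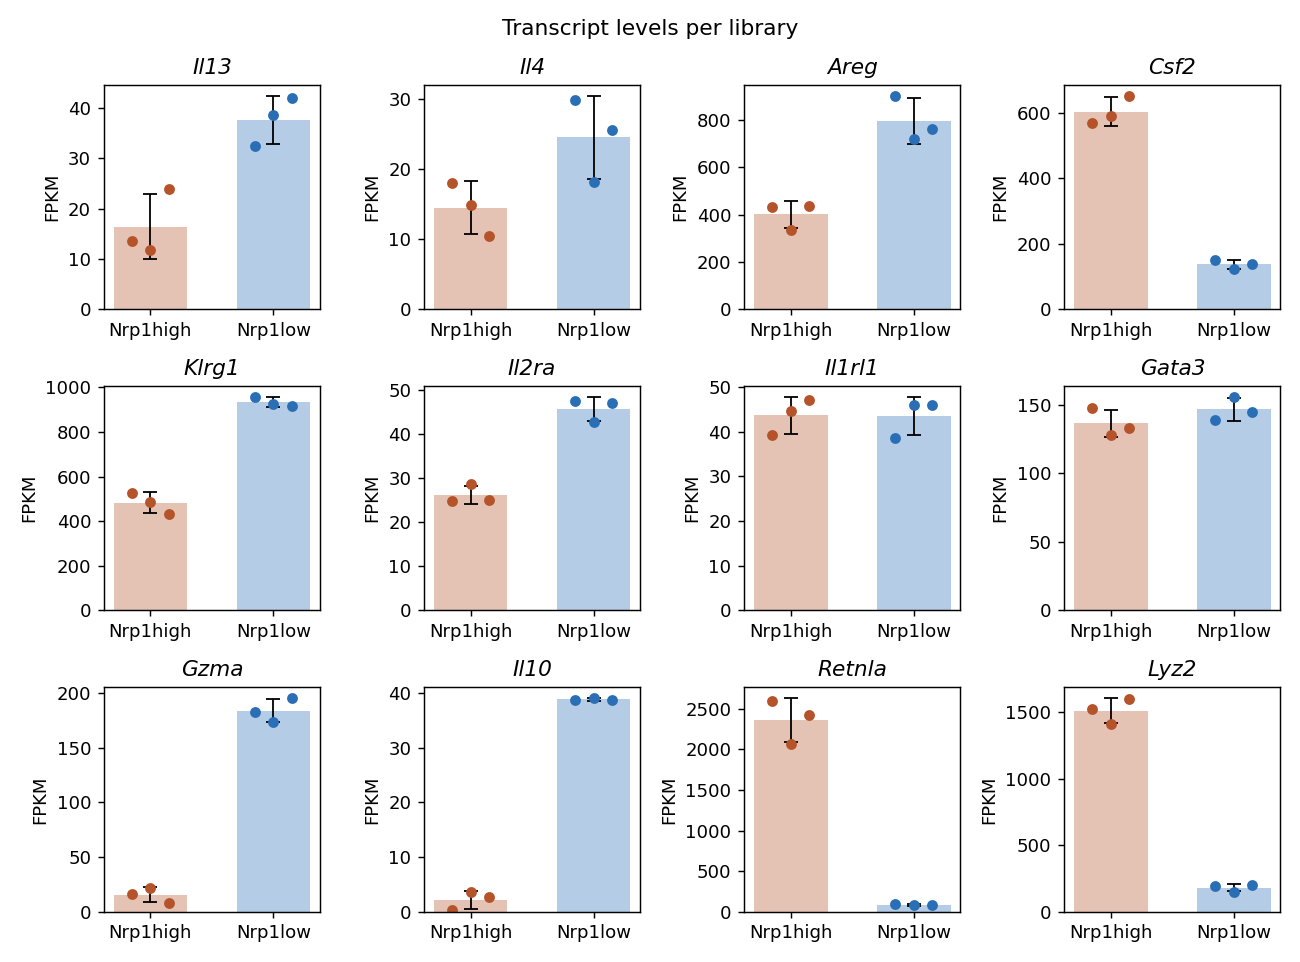
Transcript levels of 12 genes in FPKM (vertical axes, each from 0). Bars are means and error bars SDs of the 3 libraries of a group, and points are single libraries. Csf2, Retnla and Lyz2 lie higher in every Nrp1high library, Areg, Klrg1, Gzma and Il10 in every Nrp1low library, and Il1rl1 measures 43.6 FPKM in both groups.

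Receptors and transcription factors that mark ILC2s mostly did not pass the test. Of the 22 tested transcription factors, 2 rose, 1 fell and 19 did not pass, with a median of -0.015 (camera adjusted p = 0.964). Adjusted over the list alone, 3 rose and 2 fell. Gata3, the lineage factor of type 2 lymphocytes, measured 136 ± 10.1 FPKM in Nrp1high and 147 ± 8.43 in Nrp1low (limma adjusted p = 0.580), and Rora measured 59.6 ± 7.58 and 65.5 ± 0.526 FPKM (0.559). Il1rl1, which encodes ST2, measured 43.6 ± 4.06 and 43.6 ± 4.27 FPKM (0.993). Of the 29 tested receptors and surface proteins, 3 rose and 6 fell, with a median of -0.10 (camera adjusted p = 0.369), and 5 rose and 7 fell when adjusted over the list alone. Klrg1, an inhibitory receptor found on activated ILC2s, rose from 484 ± 47.6 to 935 ± 21.1 FPKM (0.95 ± 0.08, adjusted p = 0.000359). Il2ra, the alpha chain of the IL-2 receptor, measured 26.2 ± 2.11 against 45.8 ± 2.70 FPKM (0.78 ± 0.13, adjusted p = 0.00941), a call lost without Nrp1low replicate 1 (0.75) or 3 (0.76). Ramp1, a subunit of the receptor for the neuropeptide CGRP, fell from a mean of 138 to 47.1 FPKM (-1.53 ± 0.11), and the adhesion receptor Cd44 fell from 48.0 ± 4.75 to 21.5 ± 0.604 FPKM. Icos (150 ± 5.95 against 176 ± 12.0 FPKM), Il7r (84.6 ± 10.2 against 67.3 ± 5.18), Thy1 (9.88 ± 2.13 against 5.92 ± 1.55), Arg1 (661 ± 19.0 against 688 ± 18.4), Pdcd1 (455 ± 60.1 against 588 ± 28.2), Ctla4 (136 ± 26.2 against 162 ± 8.90) and Tgfbr2 (11.8 ± 1.86 against 12.7 ± 3.99), each given as Nrp1high against Nrp1low, did not pass. With quantile normalization, Mki67 (0.84) and Pdcd1 (0.42) passed the threshold. Ptgdr2 was not analysed here.

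Cytotoxic granule genes were among the genes with the highest positive log2 differences. Gzma, which encodes granzyme A, rose from 15.4 ± 6.91 FPKM in Nrp1high to 184 ± 10.9 in Nrp1low (3.60 ± 0.30, limma adjusted p = 0.000280), Gzmb rose from 2.59, 0 and 2.40 FPKM in the Nrp1high libraries to 26.0, 27.8 and 16.3 FPKM in the Nrp1low libraries, and Nkg7, a granule membrane protein, rose from 18.6 ± 5.58 to 99.2 ± 13.7 FPKM. They are the 3 of 7 tested genes of the cytotoxic and natural killer (NK) cell list that rose, also when adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.204 with an estimated correlation). This list was not called without Nrp1low replicate 2 (median 0.25 in place of 0.44), with no filter on low values (-0.0024) or with a filter at 5 FPKM (2.39, adjusted p = 0.0504). The NK cell receptor genes Ncr1 and Klrb1c were listed at 0 in every Nrp1low library, and Eomes measured 0.0899, 0 and 0.0122 and Klrd1 0, 0 and 0.698 FPKM there. These NK cell genes were picked after their values were seen. Zeros and values near 0 can be failed estimates, so their levels do not exclude NK cells. Il10, which encodes an immunoregulatory cytokine, rose from 2.17 ± 1.62 to 38.8 ± 0.228 FPKM (3.82 ± 0.41, adjusted p = 0.000978). Gimap7 (7.95 ± 2.69 against 39.3 ± 3.53 FPKM) and the histone gene H2bc11 (4.48 ± 2.68 against 28.5 ± 6.33) also rose, and Cd7, Ppic, Cd160 and Mir142hg complete the 10 highest. The surface protein gene Cd7 was listed at 0 in Nrp1high replicates 1 and 2 and at 1.03 FPKM in replicate 3, against 19.8, 17.7 and 9.48 FPKM in Nrp1low. Ppic measured 0, 2.85 and 4.51 FPKM in Nrp1high against 27.9, 32.5 and 31.2 in Nrp1low. Cd160 measured 0, 0.819 and 6.15 FPKM in Nrp1high against 18.8, 22.7 and 15.9 in Nrp1low, and lost its call without Nrp1high replicate 2 (2.90) or Nrp1low replicate 1 (3.09), 2 (2.96) or 3 (3.20) and with a constant prior variance. Gzmb, Ppic and Cd160 were not called with a pseudocount of 0.1, and these 3 and H2bc11 were not called with no filter on low values. Mir142hg, the host transcript of a microRNA, was listed at 0 in all Nrp1high libraries and measured 17.9, 25.8 and 22.9 FPKM in the Nrp1low libraries. Its zeros can be failed estimates too and are not read as its absence. H2bc11 belongs to a family of near-identical genes and its level is uncertain for that reason.

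Macrophage and monocyte genes were lower in Nrp1low cells, and so higher in the Nrp1high sort. Of the 17 tested, 14 fell, 16 when adjusted over the list alone, and none rose (median -2.97, camera adjusted p = 5.67e-24, and adjusted p = 0.0400 with an estimated correlation). Lyz2, which encodes lysozyme, fell from 1509 ± 95.5 FPKM in Nrp1high to 181 ± 27.6 in Nrp1low (-3.06 ± 0.12), and Ctss, the gene of the lysosomal protease cathepsin S, fell from 604 ± 54.7 to 126 ± 3.92 FPKM (-2.24 ± 0.09). The complement genes C1qa (73.9 ± 16.7 against 1.87 ± 1.17 FPKM), C1qb (185 ± 1.36 against 3.22 ± 1.31) and C1qc (67.9, 55.9 and 47.1 FPKM against 1.23, 0.0562 and a listed 0) had the most negative log2 differences of the named genes, at -4.78, -5.51 and -5.43. Retnla, which encodes a secreted protein of alternatively activated macrophages, fell from 2361 ± 273 to 85.0 ± 9.12 FPKM (-4.78 ± 0.11, limma adjusted p = 7.28e-07). Prnp (160 ± 15.6 against 7.62 ± 1.19 FPKM), Cd300c2 (25.0 ± 6.96 FPKM against 0.447, 2.01 and a listed 0), the lectin gene Mgl2 (41.6 ± 1.25 against 2.06 ± 1.55) and the heme oxygenase gene Hmox1 (57.6 ± 14.6 against 2.96 ± 0.301) fell with them.

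MHC class II genes and chemokines moved in the same direction as the macrophage list. All 6 tested MHC class II genes fell, also when adjusted over the list alone (median -1.74, camera adjusted p = 3.68e-11, and adjusted p = 0.0400 with an estimated correlation). Cd74, the invariant chain, fell from 2078 ± 51.2 to 668 ± 71.1 FPKM, and H2-DMb1, at 137 ± 19.8 FPKM in Nrp1high, had a log2 difference of -2.72 ± 0.16. Of 20 tested chemokines and chemokine receptors, 9 fell and 1 rose, and 10 fell and 3 rose when adjusted over the list alone (median -0.46, camera adjusted p = 8.90e-05, and adjusted p = 0.122 with an estimated correlation). Ccl17 fell from 649 ± 63.0 to 72.9 ± 14.3 FPKM (-3.15 ± 0.15), Ccl9 from 96.1 ± 18.9 to 8.63 ± 0.678 FPKM and Ccl22 from 45.2 ± 11.6 to 1.58 ± 0.783 FPKM. Ccl7 was listed at 0 in all Nrp1low libraries, against 11.8, 15.5 and 15.7 FPKM in Nrp1high. In the lipid uptake and storage list, 6 of 15 tested genes fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone (median -0.63, camera adjusted p = 0.000202, and adjusted p = 0.0923 with an estimated correlation). Lpl, the gene of lipoprotein lipase, fell from a mean of 18.0 to 1.83 FPKM (-2.76 ± 0.22), and the fatty acid transporter gene Cd36 fell from 25.9 ± 10.5 to 3.27 ± 0.864 FPKM.

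**Figure D2:**
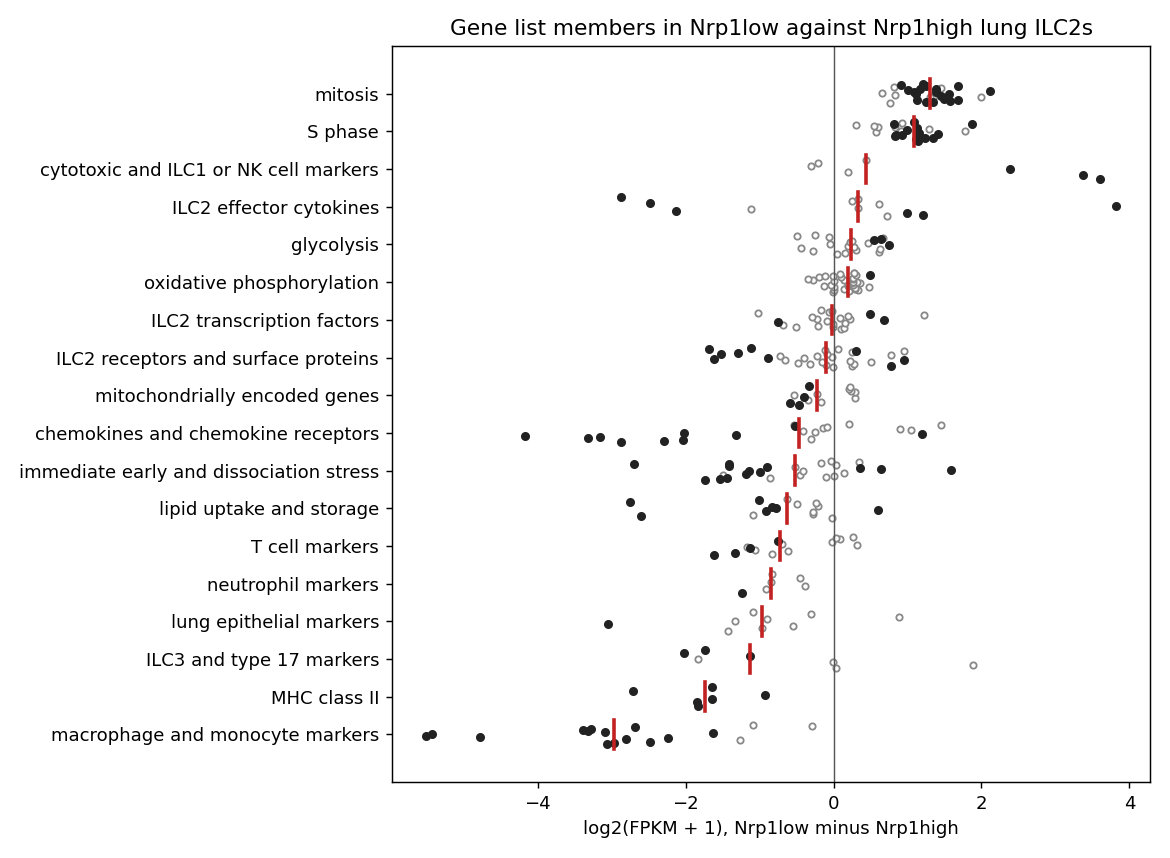
Log2 differences, Nrp1low minus Nrp1high (horizontal axis), of the tested genes of the called lists and the ILC2 lists. Filled points are genes with an adjusted p under 0.05, open points the others, and red bars list medians. The mitosis median lies at 1.31, the ILC2 transcription factor median at -0.015 and the macrophage and monocyte median at -2.97.

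Immediate early genes, which respond within minutes to receptor signals and to tissue dissociation, were called lower in Nrp1low as a list. Of 25 tested, 10 fell, 3 rose and 12 did not pass, and 15 fell and 4 rose when adjusted over the list alone (median -0.52, camera adjusted p = 7.47e-05, and adjusted p = 0.126 with an estimated correlation). Fos fell from 990.4 ± 51.3 to 296 ± 19.7 FPKM (-1.74 ± 0.08), and Zfp36, which encodes an RNA-binding protein that destabilizes cytokine transcripts, fell from 182 ± 7.46 to 68.0 ± 7.17 FPKM. The phosphatase genes Dusp5 (138 ± 10.5 against 216 ± 22.9 FPKM) and Dusp2 (12.4 ± 5.29 against 37.3 ± 3.10) rose, neither of them called with no filter on low values, Dusp5 not with a constant prior variance and Dusp2 not without Nrp1low replicate 1 (1.54). Glycolysis genes were called higher as a list, with 3 of 20 rising, 5 when adjusted over the list alone (median 0.23, camera adjusted p = 0.00587, and adjusted p = 0.126 with an estimated correlation). Ldha, which encodes lactate dehydrogenase A, rose from 559 ± 15.7 to 872 ± 42.4 FPKM, a call lost with a constant prior variance. Oxidative phosphorylation genes were called higher as a list, with 1 of 33 rising, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.00777, and adjusted p = 0.126 with an estimated correlation). That gene was Atp5a1, at 253 ± 12.6 against 356 ± 12.7 FPKM, a call lost with a constant prior variance.

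Markers of other cell types also differed between the sorts. T cell genes were called lower in Nrp1low, with 4 of 14 falling, 5 when adjusted over the list alone (median -0.72, camera adjusted p = 0.00954, and adjusted p = 0.239 with an estimated correlation), among them Cd3g at 51.0 ± 6.34 against 19.6 ± 1.97 FPKM; with a filter at 5 FPKM the list was not called (median 0.0066). Lung epithelial genes were called lower, with 1 of 9 falling, 3 when adjusted over the list alone (median -0.96, camera adjusted p = 0.00954, and adjusted p = 0.144 with an estimated correlation). That gene was Scgb1a1, a club cell secretory product, at 178 ± 27.5 against 20.8 ± 5.40 FPKM. Of the 7 tested ILC3 and type 17 genes 3 fell, 4 when adjusted over the list alone (median -1.13, camera adjusted p = 0.00954, and adjusted p = 0.204 with an estimated correlation), with Ltb at 498 ± 29.0 against 228 ± 27.9 FPKM; the list was not called without Nrp1high replicate 2 (median -1.11) or with no filter on low values (-0.12). Of the 6 tested neutrophil genes 1 fell, S100a8 at 79.5 ± 2.53 against 33.3 ± 3.60 FPKM, and 2 when adjusted over the list alone (median -0.84, camera adjusted p = 0.0213, and adjusted p = 0.204 with an estimated correlation); that list was not called without Nrp1high replicate 3 (-0.65). Liver transcripts, on a list of hepatocyte genes written after their values were seen, were above 0 in all 6 libraries for all 33 genes and lower in Nrp1low, with 20 called lower and a median of -0.82. Alb, the gene of serum albumin, measured 525 ± 7.50 FPKM in Nrp1high and 296 ± 9.87 in Nrp1low, Apoa2 measured 1415 ± 61.6 and 757 ± 29.4 FPKM, and Fabp1 measured 619 ± 45.5 and 344 ± 22.7 FPKM.

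**Figure D3:**
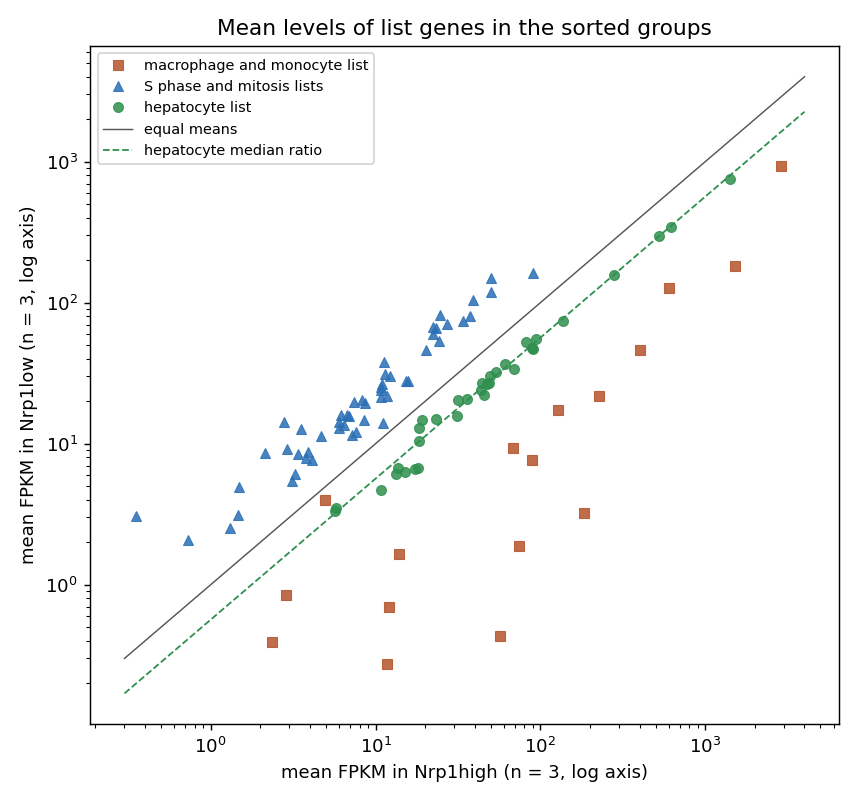
Mean FPKM in Nrp1low (vertical log axis) against mean FPKM in Nrp1high (horizontal log axis), n = 3 each, for tested genes of 4 lists, each point a gene. The solid line marks equal means and the dashed line the ratio of 0.565 at the hepatocyte median; hepatocyte genes lie along it, macrophage and monocyte genes mostly below it, and S phase and mitosis genes above the line of equal means.

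Transcripts that vary with RNA quality and library preparation differed as well. The nuclear RNA Malat1 measured 619 ± 65.7 FPKM in Nrp1high and 329 ± 49.1 in Nrp1low (-0.92 ± 0.12), and the mitochondrial ribosomal RNA mt-Rnr2 measured 5142 ± 893 and 3178 ± 561 FPKM (-0.69 ± 0.15), a call lost without Nrp1high replicate 1 (-0.60) or 2 (-0.64) or Nrp1low replicate 1 (-0.57) or 3 (-0.69), with no filter on low values and with a constant prior variance. Of 13 mitochondrially encoded genes 4 fell, 5 when adjusted over the list alone (median -0.23, camera adjusted p = 0.0272, and adjusted p = 0.473 with an estimated correlation). That list was not called without Nrp1high replicate 2 (-0.11) or Nrp1low replicate 1 (-0.19) or 3 (-0.21), nor with quantile normalization (-0.14), a constant prior variance in camera, or fry.

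Of the 42 lists, 40 had at least 3 tested genes and 15 were called by camera, 5 higher and 10 lower in Nrp1low. With an estimated correlation 4 of them held, which are mitosis, S phase, macrophage and monocyte markers, and MHC class II. The TGF-beta pathway list was not called (1 of 18 genes fell, none adjusted over the list alone, median -0.22, camera adjusted p = 0.0966). None of the 6 tested neuropilin partner genes passed, also when adjusted over the list alone (adjusted p = 0.384), and none of the 21 cholesterol synthesis genes (adjusted p = 0.708).

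The called genes were tested for enrichment in the KEGG pathways that the deposited table annotates, by one-sided exact tests. Among genes higher in Nrp1low, 7 of 310 tested pathways were enriched. DNA replication led, with 16 of its 35 tested genes (adjusted p = 1.31e-09), followed by Cell cycle with 22 of 111 (7.79e-06). Mismatch repair (7 of 21), whose called genes all belong to the called DNA replication genes too, and One carbon pool by folate (5 of 14) were also enriched. The others, Systemic lupus erythematosus, Alcoholism and Necroptosis, held 15, 15 and 11 histone genes among their 18, 18 and 17 called genes. Besides these, each held the histone variant gene Macroh2a1. Among genes lower in Nrp1low, 40 pathways were enriched. Cytokine-cytokine receptor interaction held 35 of 121 (adjusted p = 3.55e-12), Hematopoietic cell lineage 22 of 47 (3.55e-12), Phagosome 27 of 112 (1.43e-07) and Lysosome 18 of 107 (0.00326). Of the 15 called genes of Complement and coagulation cascades 6 were on the hepatocyte list, as were 4 of 10 in Cholesterol metabolism and 4 of 9 in PPAR signaling pathway. With all tested genes as background, 74 pathways were called in place of 47, 16 of them higher in place of 7. The higher count fell to 4, 3 and 4 without Nrp1high replicate 1, Nrp1high replicate 3 and Nrp1low replicate 2; DNA replication, Cell cycle and Systemic lupus erythematosus were called without any single library, Mismatch repair only without Nrp1high replicate 2 and One carbon pool by folate in no such fit, Alcoholism not without Nrp1high replicate 3 or Nrp1low replicate 2, Necroptosis not without Nrp1high replicate 1 or 3, and Complement and coagulation cascades was not called without Nrp1high replicate 3 (7 genes).

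In the authors' deposited table, 1743 genes are marked significant, 604 higher and 1139 lower in Nrp1low. Every gene so marked has a deposited change of at least 1 log2 unit and a deposited q under 0.05. Of these, 855 passed the level filter used here, and 575 were also called here, all in the same direction as in the authors' deposited table. The other 888 had a mean below 1 FPKM. On q alone, 917 of the 998 genes called here have a deposited q under 0.05.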

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

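Scaling by median ratios and camera with a constant prior variance were chosen after seeing the data. So was the trend kept in camera's variance prior in the main list test. All other settings were planned. The 998 called genes became 473 with no filter on low values, where more genes are tested, and 2707 by the authors' deposited q, for which the cause was not tested. Leaving out a Nrp1high library gave 859 to 882 and leaving out a Nrp1low library 481 to 566, each with fewer samples in the fit. Sample numbers were equal in these fits and do not explain the gap between the groups. The fit uses 1 variance per gene for both groups. The Nrp1high libraries correlated less with each other (0.901 to 0.931) than the Nrp1low libraries (0.961 to 0.968). Leaving out a Nrp1low library gives the more variable group more weight in that variance. Whether this makes the gap was not tested. The other settings gave 672 to 1015, and no gene called in both a refit and the main result changed direction. For the authors' deposited q, direction over all called genes was compared only for the 575 also marked significant, all in the same direction. Nrp1 stayed lower in Nrp1low under all settings that tested it; only by the authors' deposited q did it miss the threshold (-5.93), and its adjusted p elsewhere ranged from 0.000352 to 0.00868. The filter at 5 FPKM removed Nrp1. The 15 called lists became 4 with an estimated correlation, which is a wider null, and 29 by fry, which does not compare a list with other genes. Estimated correlations of the lists lost lay on both sides of the preset 0.01, from -0.123 (lung epithelial) to 0.394 (mitochondrially encoded). A correlation above the preset therefore does not account for every loss. For the S phase list, which held, the estimate was -0.000271, and its unadjusted camera p still went from 7.79e-16 to 0.000850. Under the other settings 14 to 21 lists were called, though the cytotoxic list was lost with no filter and with a filter at 5 FPKM, the ILC3 list with no filter, the T cell list with a filter at 5 FPKM, and the mitochondrially encoded list with quantile normalization, with camera at a constant prior variance and with fry; 11 of the 15 held in all 6 leave-one-out fits. The 47 pathways became 74 with all tested genes as background, and 41 to 54 otherwise.

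With quantile normalization mt-Cytb (0.10) and Rpl36 (0.27) reversed their sign and were no longer called; the cause was not tested. No other named gene called in the main result reversed, and no called list reversed its direction in camera. The list medians did change sign for T cell genes with a filter at 5 FPKM (0.0066) and for cytotoxic genes with no filter (-0.0024). Of 106 called named genes, 80 stayed called in all 6 leave-one-out fits; 32 lost their call with no filter, 29 with a constant prior variance, 10 with a pseudocount of 0.1, 10 with the replicate block, 3 with TMM, and 8 with quantile normalization besides those that reversed. Deviations from the group means correlated at -0.00337, 7.80e-05 and 0.0104 for replicate numbers 1, 2 and 3. Of 6 libraries, 1 was closest to its own number. No pairing by replicate number was visible, but so few libraries cannot show that same-numbered libraries were not paired. With the replicate block 708 genes, 15 lists and 52 pathways were called, with 42 of the 47 pathways kept and Mismatch repair, One carbon pool by folate, TNF signaling pathway, Th1 and Th2 cell differentiation and Transcriptional misregulation in cancer lost. Depth is unknown, so zeros and low values cannot be given a counting error.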

Other observations

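Among gene families looked at after the data were seen, 13 of 55 tested replication-dependent histone genes were called higher in Nrp1low by limma, none lower, and 42 were not called; 45 differences were positive and 10 negative, with a median of 1.01, and the family as a group was not tested. Their transcripts mostly lack poly(A) tails, and they share reads between near-identical copies. Of 9 tested Gimap genes, GTPases of lymphocytes, 2 were called higher (Gimap7 and Gimap4) and all 9 differences were positive, with a median of 0.53; Gimap4 averaged 19.9 FPKM in Nrp1high and 59.3 in Nrp1low (log2 difference 1.61 ± 0.27, SE), a call lost with no filter on low values. Of 37 proteasome subunit genes 34 had positive differences, with a median of 0.32, and 2 were called, Psmb3 and Psmc5, neither of them in all leave-one-out fits. In the other direction, 5 of 8 Clec4 lectin genes (median -2.83) and 6 of 13 cathepsin genes (median -0.69) were called lower, as were 3 of 27 T cell receptor variable segments (Trbv13-2, Trbv12-2 and Trav4-4-dv10; median -0.64, 21 negative), with Trbv13-2 at 16.5 ± 1.41 FPKM in Nrp1high and 1.70 ± 0.528 in Nrp1low. The amino acid response list was not called (5 of 16 genes higher, 1 lower, camera adjusted p = 0.115); its member Phgdh measured 36.9 ± 10.8 FPKM in Nrp1high and 81.8 ± 1.25 in Nrp1low, a call lost with no filter as well.

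All tests of explanations below were chosen after the result was seen, except the counts over other splits of the libraries. Lung lymphocyte libraries held abundant liver transcripts. The 33 hepatocyte genes took at least 0.916% of the summed FPKM in each Nrp1high library and at most 0.567% in each Nrp1low library, and 47 genes of the table had a higher mean than Apoa2. A difference in scaling between libraries is argued against, since the list median nearest to 0 under TMM, quantile and median-ratio scaling was -0.80 (bootstrap SE 0.0385). A foreign source of liver RNA or reads at different shares and expression by the sorted cells themselves both stay open and cannot be told apart: Cochran's Q, a chi-square test across genes that are not independent replicates, did not reject a common log2 difference (p = 0.807, n = 33 genes), but these genes were listed after their values were seen. A sort of ILC2s would be expected to remove hepatocytes but not RNA or reads added later.

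The macrophage and monocyte genes were lower in Nrp1low, that is, higher in the Nrp1high sort, with Chil3 at 2879 ± 202 FPKM, Lyz2 at 1509 ± 95.5 and Cd14 at 228 ± 17.8 in Nrp1high. Scaling is argued against, since all 14 called genes stayed called lower under TMM, quantile and median-ratio scaling. A lower share of ILC2s that raises all other cell types alike is not decided. The macrophage median lay 2.36 below the median of 41 non-myeloid marker genes (log2 difference -2.36, bootstrap SE 0.343). But the pseudocount shrinks the differences of markers at low levels, and the sorted cells may express some of these markers. Of the 41 differences, 27 were negative and 14 positive, and Scgb1a1 (-3.05) fell about as much as Lyz2 (-3.06). RNA of macrophages or monocytes in the Nrp1high sort and expression of these genes by Nrp1high ILC2s both stay open and cannot be told apart, since 14 of 17 list genes called lower in Nrp1low would follow from either. The unequal ratios between genes do not decide it, since the ILC2s' own level of each gene and the pseudocount also change the ratios, and a sort of ILC2s would be expected to remove macrophages but not RNA added to the sorted cells.

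S phase and mitosis genes were higher in Nrp1low, with positive differences for all 52 tested and a median of 1.15. Dilution of ILC2 RNA by other RNA in the Nrp1high libraries would lower every ILC2 gene alike and is argued against, since the ILC2 transcription factor and receptor lists had a median of -0.056 (bootstrap SE 0.0639). Scaling is argued against, since at least 32 of the 35 called genes stayed called under TMM, quantile and median-ratio scaling. As a hypothesis, found and tested on the same data, more cells in cycle among Nrp1low ILC2s may underlie the difference; cell counts or DNA content were not analysed here.

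The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of 10, called 998 genes, and the highest of the other splits called 0. For lists 1 of 10 splits called as many as 15, and the highest other called 5. For pathways 1 of 10 called as many as 47, and the highest other called 0. Each other split mixed Nrp1high and Nrp1low libraries on both sides. A difference between the real groups then adds to the spread within those sides and lowers the number of genes called. The low counts of the other splits are therefore no measure of what chance alone gives.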
